A study of Mus musculus with 12 samples.

How the data were processed

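RNA was measured in airway eosinophils of C57BL/6 wild-type mice with ovalbumin-induced allergic airway inflammation. Per the labels, mice aged 8 to 12 weeks were sensitized with 20 µg ovalbumin and 4 mg alum on days 0 and 7. They breathed nebulized 1% ovalbumin for 40 minutes on days 16 to 18 and were harvested on day 19. Eosinophils from pooled lung lavage were gated as side-scatter-high, CD45+, CD11b+, Siglec-F+ cells with low to middle CD11c and Ly6G. Each lavage was sorted into a TREM-1+ and a TREM-1- fraction, which gave 12 libraries from 6 lavages. TREM-1, encoded by Trem1, is an activating receptor of myeloid cells that signals through the adaptor DAP12, the product of Tyrobp. Total RNA was depleted of ribosomal RNA, made into stranded libraries and read as 100 bp paired ends in a single lane, per the labels' protocols.

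The deposited count table holds an estimated count for each of 39666 genes in each library. The submitters' processing notes name kallisto 0.45.0, R 4.3.0, edgeR 3.42.4 and the build GRCm39, with no role given to each. The estimated counts are whole numbers as deposited and were rounded before use, which changed nothing. A second deposited table gives log2 CPM values, which are counts scaled to a common library total, for 17934 genes. Recomputing log2 CPM from the counts of those genes with TMM factors (trimmed mean of M values) and a prior count of 1 gave the deposited values to within 5e-09. How transcripts were annotated, and whether the quantification used strand, is not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not be separated. How reads shared by near-identical genes, such as Ear1 and Ear2 or the Bcl2a1 genes, were divided is not given either, and values of such genes are uncertain. There were 26 genes with over 100 counts in total whose counts equalled those of another gene in every library. The count table holds 0 mitochondrial genome genes, so the mitochondrial list could not be tested.

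Gene symbols and NCBI gene identifiers were taken from the deposited table. Gene biotypes came from a RefSeq table of assembly GRCm38.p6, in which 38209 identifiers (96.3%) were found. Because that assembly is not the authors' build, no coordinates are given. Transcript lengths and GC content came from the longest GENCODE vM21 transcript of each symbol.

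Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, robust dispersion estimates, quasi-likelihood F test). The model had the lavage as a block and the fraction as the tested term, coded TREM-1+ minus TREM-1-. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The standard error of a log2 fold change was derived from its F statistic. Levels are CPM scaled with the TMM factors, and paired differences are on the log2 CPM scale with a prior count of 1. DESeq2 1.42.0 and limma 3.58.1 served as alternatives. Of the deposited per-sample columns, 0 were left unused.

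The pairing comes from the series' design text, which states that both fractions were sorted from the same lavage fluid. Deviations from the group means correlated within pairs at 0.49, 0.50, 0.13, 0.37, 0.25 and 0.24 in lavages 1 to 6. In 5 of the 6 lavages the TREM-1+ library correlated best with its own partner, the exception being lavage 3. In lavage 1 the lead was slight, 0.493 against 0.491 for the TREM-1- library of another lavage. The labels do not say that the 6 lavages came from separate groups of mice, so p-values measure the spread between these 6 pools. No 2 libraries of a fraction agreed within sampling noise: the chi-square per gene, which counting noise alone would put at 1, lay between 5.3 and 197 over genes with at least 20 counts. The libraries of lavages 1 and 2 were by far the closest, at 5.30 in TREM-1- and 6.95 in TREM-1+. All other values were 21.1 or more. Whether lavages 1 and 2 are independent pools is therefore uncertain, and the 6 pairs may hold less information than 6 independent ones.

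Before the data were examined, 34 gene lists were fixed, 24 of pathways or cell functions and 10 of cell-type markers. Lists with at least 5 tested members (32 lists) were tested with camera at a preset inter-gene correlation of 0.01, which asks whether a list's genes rank higher or lower than all other genes. Adjusted p-values of lists are Benjamini-Hochberg values over the 32 lists. Beside it stand camera with an estimated correlation, fry, and the members called when p is adjusted over all genes or adjusted over the list alone. With an estimated correlation 1 of the 16 called lists, the interferon response, stayed below 0.05, and each other list's adjusted p with an estimated correlation is given beside its result. By fry, which asks whether a list's own genes move, on balance, one way, 15 lists passed.

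The rule for named genes was also fixed before the data were examined. It takes Trem1, and then the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM and the same sign in 6 of 6 pairs, leaving out predicted, Rik, pseudogene, ribosomal model, sex-linked and variable-region genes. It adds Siglecf, Ccr3, Il5ra, Epx and Prg2, and for each list up to 2 called members per direction with the smallest p. For marker lists, and for lists with no called member, it adds the 3 members of highest mean CPM. Some genes that the rule takes are left out of the text without replacement.

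Alternatives fixed before the data were examined were a model without the lavage block, RLE and upper-quartile factors, library totals alone, no filter on low counts, a mean of at least 5 CPM, DESeq2, limma-voom, limma-trend on the deposited log2 CPM, an adjusted p of 0.01, each lavage left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were fits on lavages 1 and 2, on lavages 3 to 6 and on lavages 1, 2, 5 and 6, a fit on protein-coding genes, and a T-cell marker score as a covariate. Also chosen then was a comparison of 8 measures of the libraries, such as the total count, between the fractions of each lavage by exact sign-flip permutation, with Benjamini-Hochberg adjustment over the 8.

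The procedure was tested on 5 simulated tables drawn from the real lavage means, library sizes and dispersions, with 200 genes changed in each. Over 17961 to 17986 tested genes, it recovered 31.6% of genes changed 1.25-fold, 58.2% of those changed 1.5-fold and 75.2% of those changed 2-fold between the TREM-1+ and TREM-1- libraries. Of its 576 calls over the 5 tables, 40 (6.94%) were unchanged genes. Library totals ran from 8626701 to 21234053 counts, and intervals here cover the spread between lavages and counting error, without a correction for PCR copies.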

Results

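Transcripts of airway eosinophils that carried TREM-1 at the surface were compared with those of eosinophils from the same lavage that did not, during allergic inflammation in mice. Each fraction had 6 libraries. Total counts ran from 16513387 to 21234053 in TREM-1- libraries and from 8626701, in lavage 4, to 19274912 in TREM-1+ libraries. Of 39666 genes in the table, 18302 passed the filter on low counts and were tested.

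Trem1, which encodes the sorted antigen and so checks the sort, was higher in the TREM-1+ library of all 6 lavages. From lavage 1 to lavage 6, the TREM-1- libraries held 32.6, 24.9, 33.3, 42.1, 18.4 and 32.8 CPM, and their TREM-1+ partners 92.1, 86.3, 81.1, 130.7, 73.5 and 95.2 CPM. The mean was 30.7 ± 8.12 CPM (SD, n = 6) in TREM-1- and 93.1 ± 20.0 CPM (SD, n = 6) in TREM-1+ eosinophils. The log2 fold change was 1.62 ± 0.07 (SE, edgeR adjusted p = 7.36e-15). The exact two-sided sign-flip permutation test of the 6 paired differences gave p = 0.0312, the smallest that its 64 sign patterns allow. Trem1 transcript was also present in each TREM-1- library, and the paired difference ranged from 2.43-fold to 3.98-fold. As the sorted antigen, Trem1 is no finding between the fractions.

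In TREM-1+ eosinophils 37 of 48 genes of the interferon response list were lower than in TREM-1- eosinophils of the same lavage and 0 were higher (camera adjusted p = 1.68e-69, adjusted p = 0.00481 with an estimated correlation). Among genes of at least 5 CPM that moved the same way in 6 of 6 pairs, the largest rise was in S100a8 (log2 fold change 2.35 ± 0.19, SE), which encodes a subunit of calprotectin. Besides Trem1, next came Pald1 (1.76 ± 0.17), Fn1 (1.49 ± 0.21) for fibronectin, S100a9 (1.45 ± 0.09) for the other subunit of calprotectin, Lrp1 (1.39 ± 0.09), an endocytic receptor, and Il6st (1.34 ± 0.20), the signal-transducing receptor chain gp130. Cd3e (1.31 ± 0.20), a T cell receptor chain, Ccl24 (1.29 ± 0.26) for the chemokine eotaxin-2, complement C3 (1.21 ± 0.15), the cytokine gene Il1b (1.19 ± 0.07) and Retnla (1.18 ± 0.06) completed the 12. Adjusted p-values (edgeR) of these genes ran from 7.36e-15 for Trem1 to 0.00842 for Fn1. Some of these genes are also on the lists of markers of other cell types described below. S100a8 and S100a9 are neutrophil markers there, Fn1 a monocyte and interstitial macrophage marker and Cd3e a T and innate lymphoid cell marker. In TREM-1+ libraries Fn1 (69.3 ± 65.3 CPM), Cd3e (7.45 ± 6.09 CPM) and Ccl24 (8.91 ± 8.29 CPM) varied widely between lavages (SD, n = 6). Il1b rose from 20.9 ± 2.60 to 47.7 ± 4.45 CPM, Retnla from 199.7 ± 92.7 to 447 ± 197 CPM and S100a8 from 1.70 ± 0.55 to 8.72 ± 2.48 CPM (SD, n = 6).

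The largest falls included Tgm2 (log2 fold change -1.64 ± 0.11, SE), which encodes transglutaminase 2. Ear1 (-1.50 ± 0.16), an eosinophil-associated ribonuclease whose reads may be shared with its close copies, the exchange factor gene Arhgef10l (-1.47 ± 0.16) and the ubiquitin ligase gene Nedd4 (-1.18 ± 0.12) followed. Other large falls were in the small RNA Scarna10 (-1.11 ± 0.12), Cd300ld3 (-1.09 ± 0.12), Lypd6 (-1.05 ± 0.18), Atp8b5 (-1.01 ± 0.17), Tmem119 (-0.96 ± 0.08), the inhibitory receptor gene Lair1 (-0.95 ± 0.09) and Plac8 (-0.94 ± 0.06). Their edgeR adjusted p-values lay between 7.85e-13 for Plac8 and 0.00311 for Ear1. Tgm2 fell from 516.8 ± 72.9 to 167.8 ± 35.8 CPM and Plac8 from 67.9 ± 35.4 to 34.9 ± 16.6 CPM (SD, n = 6). In lavages 3 to 6 alone Fn1 (log2 fold change 1.51, adjusted p = 0.127) and Ear1 (-1.46, adjusted p = 0.095) were not called. The same held for Il6st (1.49, adjusted p = 0.137) and Ccl24 (0.69, adjusted p = 0.739) in lavages 1 and 2 alone. Without lavages 3 and 4 Fn1 was not called either (1.44, adjusted p = 0.0845). These fits hold fewer libraries, and except in Ccl24 the folds stayed close to those of all 6 lavages. The NCBI gene identifiers in the deposited table were 58217 for Trem1, 20201 for S100a8, 20202 for S100a9, 27355 for Pald1, 14268 for Fn1, 16176 for Il1b, 57262 for Retnla, 21817 for Tgm2, 13586 for Ear1, 72754 for Arhgef10l and 17999 for Nedd4.

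**Figure D1:**
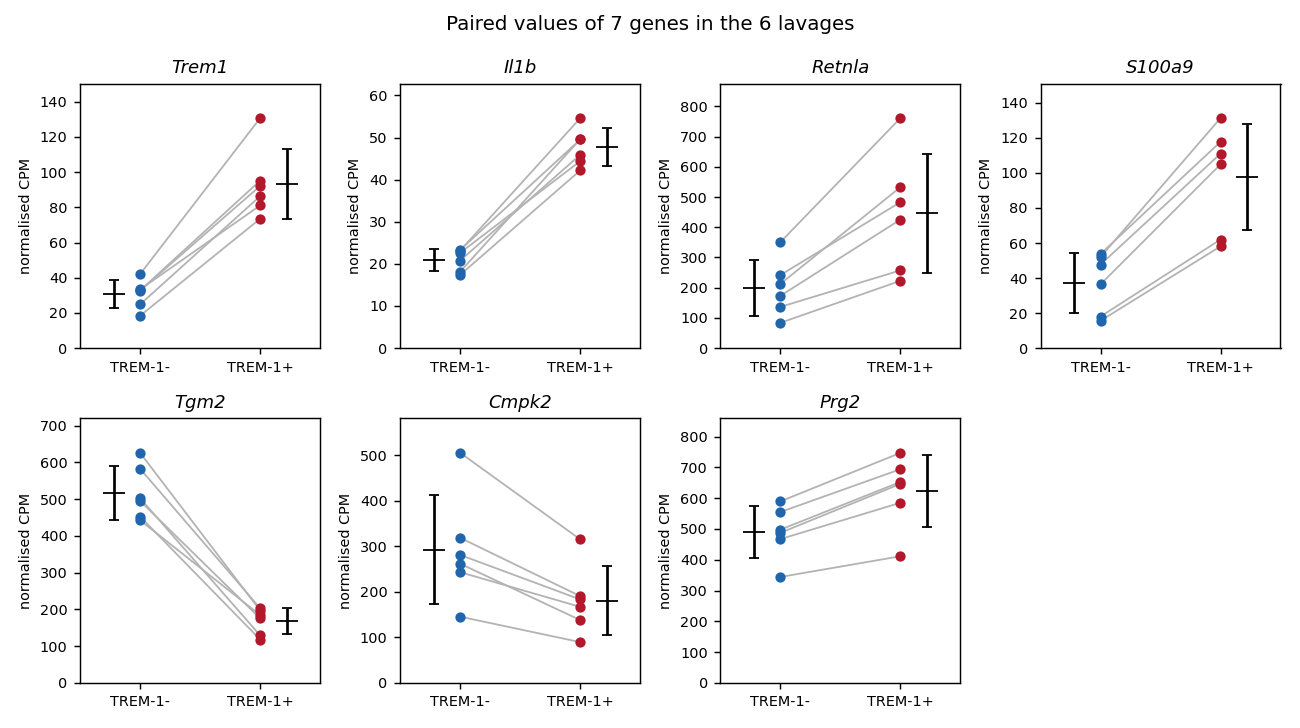
Normalised CPM (y axis) of 7 genes in TREM-1- and TREM-1+ libraries (x axis), with grey lines joining the fractions of a lavage and black marks giving the mean and SD of 6 libraries. Trem1, Il1b, Retnla, S100a9 and Prg2 were higher, and Tgm2 and Cmpk2 lower, in the TREM-1+ library of all 6 lavages.

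In all, 1797 genes (9.82% of those tested) were called by edgeR at an adjusted p below 0.05, of which 568 were higher and 1229 lower in TREM-1+ eosinophils. Most changes were small, with a median absolute log2 fold change of 0.27 among called genes. A change of at least 2-fold was seen in 82 called genes, 62 higher and 20 lower. That count was 139 with library totals alone, 138 with no filter on low counts and 34 at a mean of at least 5 CPM. The higher genes had lower expression, with a median of 28.1 CPM against 128 CPM for the lower genes. All 6 pairs had the same sign in 1496 of the called genes and in 13.4% of all tested genes, where chance gives 3.12%.

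The counts depended on comparing the fractions within a lavage. Lavage accounted for 60.3% of the variance of log2 CPM and the fraction for 9.34%, and without the lavage block 83 genes were called, 27 higher and 56 lower, with 11 at 2-fold or more. These raw shares are not directly comparable, since lavage has more levels than the fraction and labels of no effect would also take up a share. Lavages 1 and 2 stood apart from lavages 3 to 6 on the first principal component, which held 28.8% of the variance. Fitted alone, lavages 1 and 2 gave 1567 genes (425 higher, 1142 lower) and lavages 3 to 6 gave 1168 genes (366 higher, 802 lower). The libraries of lavages 1 and 2 lay far closer to each other than any others, so the first count may be too high. Of the 1557 genes called in lavages 1 and 2 and tested in both, 91.7% had the same sign in lavages 3 to 6, against 60.5% of all genes tested in both. Without lavages 3 and 4, which held the library of the lowest total and those with the largest shares of Gm26917 and Zrsr2-ps1 counts, 1291 genes were called. The make-up of the libraries also moved with the fraction. In TREM-1+ libraries the total count and the share of the 10 largest genes (12.7 ± 2.77% against 15.4 ± 4.31%, SD, n = 6) were lower in 6 of 6 pairs. The share of 7SL RNA (3.87 ± 1.52% against 5.21 ± 2.14%) was lower, and those of Zrsr2-ps1 (1.42 ± 1.52% against 0.624 ± 0.493%) and of protein-coding genes (86.1 ± 2.87% against 83.1 ± 6.06%) higher, in 5 of 6 pairs. Of 8 such measures 0 passed the exact two-sided sign-flip permutation test after adjustment (adjusted p 0.0832 to 0.281), whose smallest unadjusted p is 0.0312. Measures that moved 1 way in 6 of 6 pairs reached that p and still had an adjusted p of 0.0832. The test could therefore hardly pass any measure, and does not show that the libraries were alike. TREM-1+ libraries had larger scaling factors than their partners in 6 of 6 pairs, and with library totals alone the median log2 fold change of all genes became 0.13 in place of 0.00 and the split became 1880 higher against 376 lower, so that 16.7% in place of 68.4% of called genes were lower. Small changes are relative to the median gene. Among genes no longer called with library totals alone were Siglecf, Il5ra, Tyrobp, Cox7a2l, Cyp51, Lgals3, Alox5ap, Ptafr, Tap1, Mcl1, Mki67 and Cd24a.

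**Figure D2:**
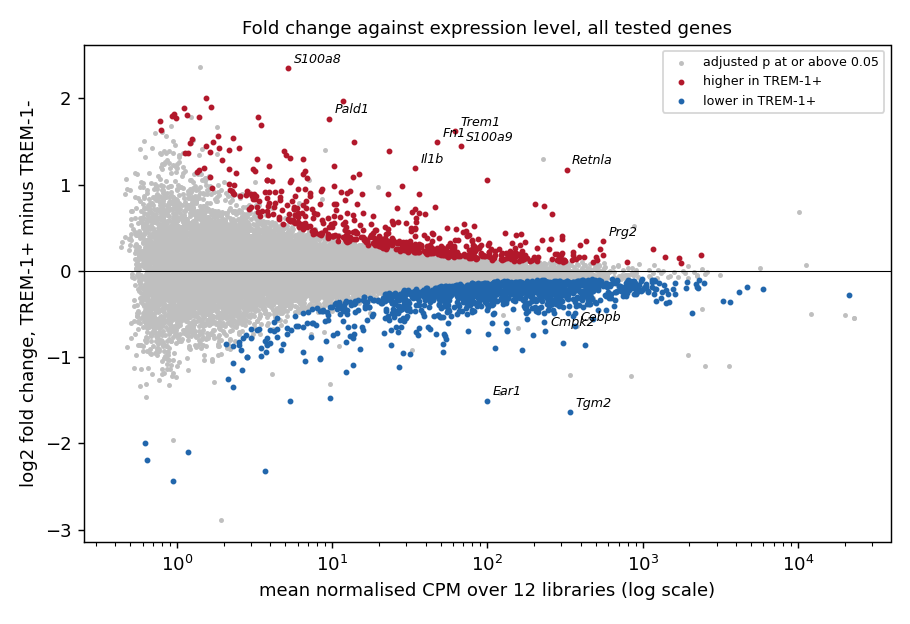
Log2 fold change of TREM-1+ minus TREM-1- libraries (y axis) against mean normalised CPM over 12 libraries (x axis, log scale) for 18302 tested genes, with called genes in red (568 higher) and blue (1229 lower) and others in grey. Rises of 2-fold or more lay mostly at low CPM, while most called falls were under 2-fold.

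The interferon response list, genes induced by interferons and active in antiviral defence, had the clearest shift of the 32 lists tested. Of its 48 members 37 were called lower and 0 higher (40 lower and 2 higher adjusted over the list alone), and the median log2 fold change was -0.37 (camera adjusted p = 1.68e-69, adjusted p = 0.00481 with an estimated correlation). The list's median was below 0 in each of the 6 lavages, from -0.29 in lavage 5 to -0.42 in lavage 4, and it was -0.35 in the fit of lavages 1 and 2 and -0.39 in that of lavages 3 to 6. Cmpk2, which encodes a mitochondrial nucleotide kinase, fell from 292 ± 119 to 180.5 ± 75.5 CPM (log2 fold change -0.70 ± 0.04, SE), and Ifi47, an interferon-induced GTPase gene, from 165 ± 67.3 to 102.3 ± 45.2 CPM (-0.70 ± 0.04). With library totals alone the median of the list was -0.24, and the median of all genes rose to 0.13.

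Genes of eosinophil identity were lower as a list, by small amounts. Of 22 members tested, 12 were called lower and 3 higher (14 lower and 3 higher adjusted over the list alone), with a median log2 fold change of -0.12 (camera adjusted p = 9.81e-06, adjusted p = 0.201 with an estimated correlation). Ccr3, the eotaxin receptor gene, fell from 985 ± 126 to 816 ± 114 CPM (log2 fold change -0.27 ± 0.03, SE) and Il1rl1, the interleukin-33 receptor gene, fell from 643 ± 59.1 to 526 ± 60.9 CPM (-0.29 ± 0.03). Siglecf, whose product was used in the gate, had a log2 fold change of -0.14 ± 0.03 (adjusted p = 0.00541), and Il5ra, the interleukin-5 receptor gene, -0.15 ± 0.04 (adjusted p = 0.00899). Neither passed the edgeR test with library totals alone (-0.01, adjusted p = 0.932, and -0.03, adjusted p = 0.768), and the adjusted p of Il5ra was 0.0598 without lavage 1 and 0.079 without lavages 3 and 4. In lavages 3 to 6 alone the adjusted p was 0.21 for Siglecf and 0.138 for Il5ra. Alox15, the lipoxygenase gene, rose by a log2 fold change of 0.19 ± 0.03 at a mean of 2391 CPM, and the transcription regulator gene Id2 by 0.20 ± 0.03.

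The granule protein list was split. Of 9 members tested, 3 were called higher and 2 lower (4 and 4 adjusted over the list alone), and the median log2 fold change, 0.06, the mean, -0.28, and the test (upward, camera adjusted p = 0.976) differed in sign. Prg2, encoding major basic protein, rose from 490 ± 84.9 to 623 ± 117 CPM (log2 fold change 0.34 ± 0.03, SE) and Serpinb2 from 379 ± 126 to 479 ± 152 CPM (0.34 ± 0.03), whereas Ear1 and Prg3 (-0.64 ± 0.15, adjusted p = 0.125 in lavages 3 to 6 alone) fell. Epx, the eosinophil peroxidase gene, had 42.3 ± 11.4 CPM in TREM-1+ and 40.1 ± 5.06 CPM in TREM-1- eosinophils (edgeR adjusted p = 0.785, higher in 4 of 6 pairs). Without lavage 5 the list was called lower (adjusted p = 0.00993), and it was also called lower in the fit of lavages 1 and 2 (adjusted p = 0.0482).

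Activation lists moved in parts. In the list of activated tissue eosinophil genes, 10 of 26 members were lower and 3 higher (12 and 3 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.00196, adjusted p = 0.189 with an estimated correlation). Cd69, an early activation antigen gene, fell by 0.91 on the log2 scale and Ahr, the aryl hydrocarbon receptor gene, fell by 0.37, while Il1b rose and Clec7a, the beta-glucan receptor gene, rose by 0.38. Clec7a was not called in lavages 1 and 2 alone (log2 fold change 0.04, adjusted p = 0.921) or without lavages 3 and 4 (0.23, adjusted p = 0.098). Of 18 genes of TREM-1 signalling, 7 were lower and 1, Trem1 itself, higher (9 and 3 adjusted over the list alone). Their median was -0.10, the mean 0.01 and the test downward (camera adjusted p = 0.746). These values include Trem1 (log2 fold change 1.62), whose rise was set by the sort. The mean and the test therefore cannot tell whether the other members fell together. Vav3 fell by 0.41 and Tyrobp, which encodes the adaptor of TREM-1, fell by 0.23, although with library totals alone Tyrobp was not called (-0.10, adjusted p = 0.110). In lavages 1 and 2 alone the list was called lower (adjusted p = 0.0217).

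Inflammatory and secreted factor genes went both ways. In the NF-kB list 8 of 45 members were higher and 7 lower (10 and 10 adjusted over the list alone, camera adjusted p = 0.0941, or 0.0257 in lavages 3 to 6 alone). Beside Il1b, Csf1, the macrophage growth factor gene, rose from 259.6 ± 47.4 to 343 ± 55.9 CPM (log2 fold change 0.41 ± 0.03, SE), while the early response gene Ier3 (-0.65 ± 0.08) and the NF-kB subunit gene Rel (-0.27 ± 0.04) fell. Among 36 secreted factors, 5 were higher and 6 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.77), those with the smallest p being Il1b and Csf1 among the higher and the chemokine gene Ccl6 (-0.37 ± 0.03, at a mean of 3641 CPM) and Tgfbi (-0.37 ± 0.04) among the lower. In the type 2 cytokine response list 8 of 31 were higher and 7 lower (11 and 9 adjusted over the list alone, camera adjusted p = 0.125, or 0.0457 without lavage 2). Retnla and Il13ra1 (0.73 ± 0.08), an interleukin-13 receptor chain gene, had the smallest p of the higher members, and Pim1 (-0.32 ± 0.03) and Socs1 (-0.33 ± 0.04), a feedback inhibitor of cytokine signalling, of the lower.

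Adhesion and chemotaxis genes were lower as a list. Of 37 members, 15 were lower and 4 higher (21 and 6 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 4e-11, adjusted p = 0.189 with an estimated correlation). C5ar1, the receptor gene for complement C5a, fell from 247 ± 32.3 to 177 ± 18.7 CPM (log2 fold change -0.48 ± 0.04, SE). Cxcr2 (0.22 ± 0.03) and S1pr1 (0.78 ± 0.15), which encodes a sphingosine-1-phosphate receptor, rose, although S1pr1 was not called in lavages 1 and 2 alone (0.48, adjusted p = 0.23). In the pattern recognition list 11 of 40 were lower and 3 higher (12 and 5 adjusted over the list alone). Its median was -0.03 and its mean 0.03 (downward, camera adjusted p = 0.0274, adjusted p = 0.286 with an estimated correlation). That call was lost without the lavage block (adjusted p = 0.218), without lavage 1 (0.0742), without lavage 2 (0.0547), in lavages 3 to 6 alone (0.291) and with protein-coding genes alone (0.0597). Lilrb4a (-0.49 ± 0.04) and Cd300lf (-0.30 ± 0.03), inhibitory receptor genes, fell, and Tlr13 (0.20 ± 0.04) and, with the limits given above, Clec7a rose.

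The glycolysis and the ribosomal protein lists were lower by small amounts. In the hypoxia and glycolysis list 14 of 37 were lower and 1 higher (20 and 1 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 6.05e-05, adjusted p = 0.189 with an estimated correlation). The glycolytic genes Eno1 (-0.29 ± 0.04) and Ldha (-0.27 ± 0.04) fell, and Egln3 rose (0.34 ± 0.09), a call lost without lavage 2 (adjusted p = 0.0534), without lavage 5 (0.0517) and in lavages 3 to 6 alone (0.146). Of 85 cytosolic ribosomal protein genes, 28 were lower and 1 higher (42 and 2 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 2.06e-09, adjusted p = 0.501 with an estimated correlation, fry adjusted p = 0.138). The list was not called in lavages 3 to 6 alone (adjusted p = 0.0741). Its median was -0.08 without lavage 2, and by lavage ran from -0.34 in lavage 2 to 0.002 in lavage 5. Fau (-0.27 ± 0.04) fell, and Rpl3 (0.18 ± 0.05, adjusted p = 0.0273) rose, a call that was lost without lavage 3 (0.102), lavage 4 (0.117), lavage 5 (0.108) or lavage 6 (0.102), without both lavages 3 and 4 (0.351), with limma-voom (0.0627) and in lavages 1 and 2 alone (-0.02, adjusted p = 0.921). With library totals alone the medians of the identity, adhesion, glycolysis and ribosomal lists all lay between -0.00 and 0.01, below the median of all genes by about as much as before.

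Of 78 nuclear genes of oxidative phosphorylation, 7 were lower and 0 higher (7 and 0 adjusted over the list alone), among them Cox8a (-0.35 ± 0.06) and Cox7a2l (-0.30 ± 0.06). The list's camera adjusted p was 0.0896, or 0.0474 without lavage 4, 0.0241 without lavage 5, 0.0435 without lavages 3 and 4 and 0.000124 in lavages 1 and 2 alone. The NADPH oxidase and antioxidant list had 10 of 27 members lower and 1 higher (15 and 3 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.00196, adjusted p = 0.375 with an estimated correlation, 0.0977 in lavages 3 to 6 alone). Txnrd1 (-0.40 ± 0.04) and Gpx1 (-0.30 ± 0.04) fell, and Slc7a11 (0.22 ± 0.04), the cystine transporter gene, rose. Of 32 apoptosis and survival genes, 13 were lower and 0 higher (14 and 0 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.000405, adjusted p = 0.189 with an estimated correlation). Both examples with the smallest p, Pim1 and Mcl1 (-0.24 ± 0.03), encode survival factors.

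In the immediate early and heat shock list 9 of 38 were lower and 3 higher (12 and 4 adjusted over the list alone), with a median of -0.02 (camera adjusted p = 0.043, adjusted p = 0.375 with an estimated correlation). The call was lost without the block (adjusted p = 0.21), without lavage 1 (0.0934), without lavage 2 (0.058), in lavages 3 to 6 alone (0.252), at a mean of at least 5 CPM (0.0577) and with protein-coding genes alone (0.0597). Zfp36 (-0.47 ± 0.05) and Dusp6 (-0.37 ± 0.03) fell, and Dusp5 (0.37 ± 0.05) and Jun (0.25 ± 0.04) rose. In libraries in which T and innate lymphoid (median 0.81) and dendritic cell markers (0.54) were also higher, the cell cycle list was higher, with 4 of 35 members higher and 1 lower (4 and 1 adjusted over the list alone) and a median of 0.21 (camera adjusted p = 0.018, adjusted p = 0.181 with an estimated correlation). Among the 16 members with a mean of at least 5 CPM the call was lost (adjusted p = 0.0577). Its higher members included the replication genes Rrm1 (0.65 ± 0.16) at 7.99 CPM and Mcm2 (0.89 ± 0.24) at 3.13 CPM, each higher in 5 of 6 pairs, and Mki67 was lower (-0.17 ± 0.06, adjusted p = 0.0475). Mki67 was not called when any lavage was left out (adjusted p 0.0523 to 0.246), and Mcm2 was not called without lavage 1 (0.0664), lavage 5 (0.0674) or lavage 6 (0.0625) or in lavages 3 to 6 alone (0.149). Rrm1 was not called in lavages 1 and 2 alone (0.51, adjusted p = 0.0765) or without lavages 3 and 4 (0.38, adjusted p = 0.186).

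The other functional lists were not called. In the stress response list 5 of 37 members were higher and 3 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.184). Cebpb, a transcription factor gene, fell from 448 ± 59.0 to 286 ± 29.6 CPM (log2 fold change -0.64 ± 0.03, SE), Xbp1 fell (-0.34 ± 0.03), and Sel1l (0.30 ± 0.04, adjusted p = 0.0597 in lavages 1 and 2 alone) and Slc7a11 rose. Of 23 cholesterol synthesis genes, 4 were lower and 0 higher (4 and 0 adjusted over the list alone), including Cyp51 (-0.23 ± 0.05, adjusted p = 0.0631 without lavage 6 and 0.177 in lavages 1 and 2 alone). Their median was 0.07, their mean 0.02 and the test downward (camera adjusted p = 0.994). In the lipid and lysosome list 7 of 33 were higher and 4 lower (9 and 7 adjusted over the list alone, camera adjusted p = 0.0717, or 0.0157 without lavage 1, 0.00761 without lavage 2 and 0.000503 in lavages 3 to 6 alone). Ctss (0.48 ± 0.08) and Atp6v0d2 (1.39 ± 0.28) rose, and Ctsd (-0.32 ± 0.03) and Lgals3 (-0.21 ± 0.04) fell. Atp6v0d2 was called neither in lavages 1 and 2 alone (1.21, adjusted p = 0.197) nor in lavages 3 to 6 alone (1.44, adjusted p = 0.0652). Of 23 eicosanoid genes, 6 were lower and 1 higher (6 and 2 adjusted over the list alone, camera adjusted p = 0.101, or 0.0432 in lavages 1 and 2 alone), with Alox5ap (-0.23 ± 0.03) and Ptafr (-0.23 ± 0.03) lower and Alox15 higher.

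Of 20 antigen presentation and costimulation genes, 4 were higher and 4 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.377, or 0.0453 without lavage 1 and 0.0425 in lavages 3 to 6 alone). H2-K1 (0.16 ± 0.03) and H2-Ab1 (1.13 ± 0.28) rose, and Tap1 (-0.24 ± 0.03) and Cd274 (-0.32 ± 0.05), which encodes PD-L1, fell. The call of H2-Ab1 was lost without lavage 1 (1.14, adjusted p = 0.0563), without lavage 3 (0.97, adjusted p = 0.0973) and without both lavages 3 and 4 (1.24, adjusted p = 0.0595). Of 26 tissue remodelling genes, 5 were higher and 6 lower (7 and 7 adjusted over the list alone). Their median was -0.02 and their mean 0.03 (downward, camera adjusted p = 0.377, or 0.0166 without the block). Anxa1 (0.35 ± 0.05) and Serpinb2 rose, and Mmp9, encoding a matrix metalloproteinase, fell from 275 ± 30.8 to 185 ± 37.1 CPM (-0.59 ± 0.05), as did Adam8 (-0.27 ± 0.03).

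**Figure D3:**
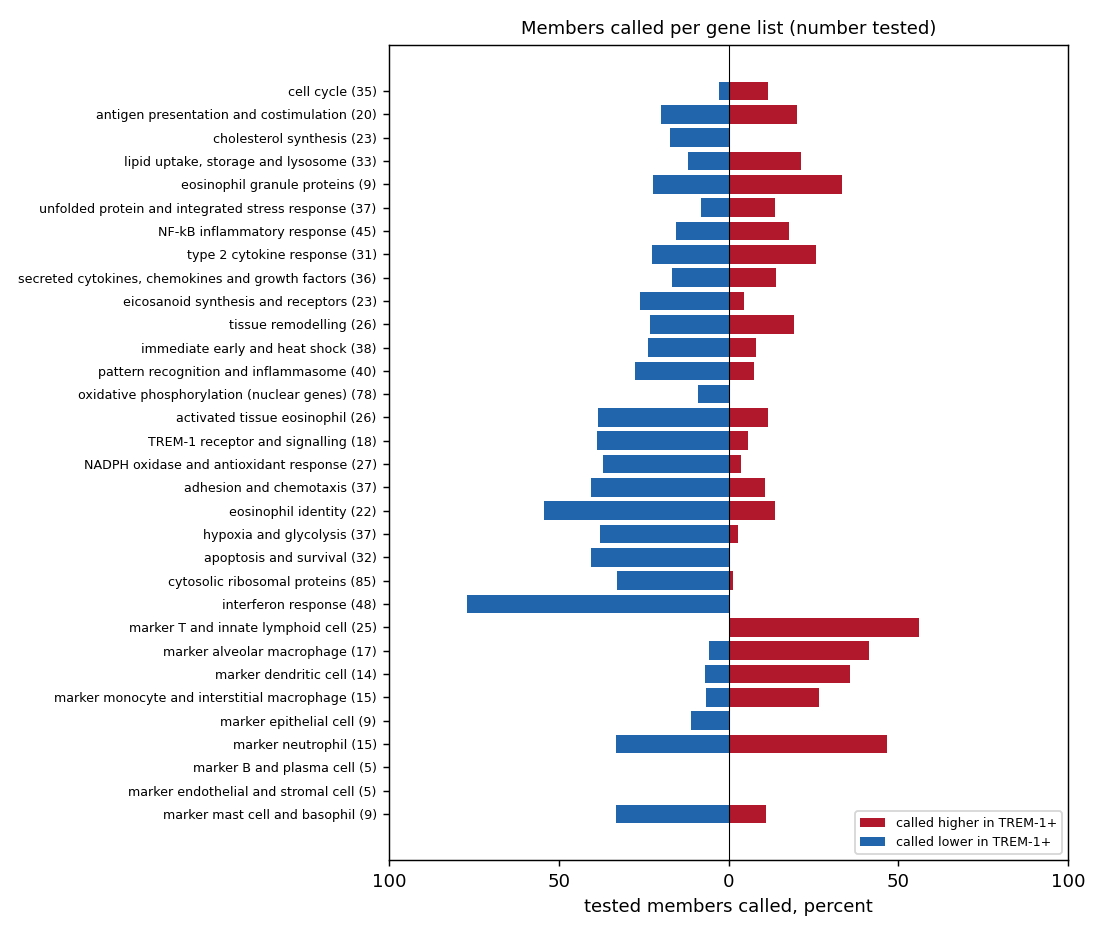
Percent of tested members (x axis) called higher (red, to the right) or lower (blue, to the left) in TREM-1+ libraries for the 32 lists with at least 5 tested members (y axis, number tested in brackets). The interferon response list has 37 of 48 members lower, and the T and innate lymphoid marker list 14 of 25 higher.

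Of 9 tested lists of markers of other cell types, camera called 5, and 0 with an estimated correlation. For these lists the TREM-1+ mean is given before the TREM-1- mean where levels are set against each other. Of 25 T and innate lymphoid cell markers, 14 were higher in TREM-1+ libraries and 0 lower (21 and 0 adjusted over the list alone), with a median log2 fold change of 0.81 (camera adjusted p = 4.06e-16, adjusted p = 0.154 with an estimated correlation). The list's median was 0.29 over 13 members in the fit of lavages 1 and 2 (adjusted p = 0.0432) and 0.94 over 26 members in that of lavages 3 to 6. Their levels were low: the summed CPM of the list was 164 ± 108 in TREM-1+ and 98.3 ± 56.6 in TREM-1- libraries (SD, n = 6). Cd3e had 7.45 ± 6.09 against 3.18 ± 3.005 CPM and Cd6 5.06 ± 4.19 against 1.61 ± 1.72 CPM. The members of highest mean were Tcf7 (21.5 against 13.9 CPM, called), Il7r (11.1 against 6.12 CPM, called) and Rora (16.4 against 14.8 CPM, adjusted p = 0.462). In lavages 1 and 2 alone neither Tcf7 (log2 fold change 0.31, adjusted p = 0.401) nor Il7r (2.01, adjusted p = 0.122) was called, and Tcf7 was not called without lavages 3 and 4 (0.38, adjusted p = 0.0519). These libraries are the ones in which the interferon, identity and other lists described above were lower and the cell cycle list higher.

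Of 17 alveolar macrophage markers, 7 were higher and 1 lower (9 and 4 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.000654, adjusted p = 0.181 with an estimated correlation). The call was lost without the block (adjusted p = 0.21), without lavage 5 (0.0759) and in lavages 1 and 2 alone (0.915, median 0.28). Car4, a carbonic anhydrase gene, rose from 201 ± 44.3 to 318 ± 71.5 CPM and Pparg from 4.16 ± 1.40 to 7.89 ± 1.59 CPM, while Ear1 was lower. Itgax had 895 ± 103 against 908 ± 53.9 CPM (edgeR adjusted p = 0.771). Chil3 had 305 ± 245 in TREM-1+ against 151 ± 171 CPM, higher in 6 of 6 pairs but not called by edgeR (adjusted p = 0.0877). It was called by DESeq2 (0.00183), limma-voom (2.73e-05), limma-trend (3.12e-05), edgeR with no filter (6.15e-196) and edgeR in lavages 1 and 2 alone (1.63e-35). The last 2 values are implausibly small for the spread of Chil3 and were not taken as strength of evidence. With no filter its log2 fold change was 1.31, against 1.30 as reported. Of 15 monocyte and interstitial macrophage markers, 4 were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.00962, adjusted p = 0.181 with an estimated correlation, 0.0946 without the block, 0.0732 in lavages 1 and 2 alone and 0.0577 at a mean of at least 5 CPM). By lavage the median of that list ran from 0.04 in lavage 2 to 0.30 in lavage 5. Fn1 had 69.3 ± 65.3 against 25.9 ± 27.5 CPM. Lyz2 had 20.0 ± 15.5 against 9.60 ± 8.09 CPM, a call lost without lavage 1 (adjusted p = 0.0788), without lavage 3 (0.108) and in lavages 3 to 6 alone (0.173). In those fits the log2 fold change of Lyz2 was 1.105, 1.018 and 1.014, against 1.129 in all 6 lavages. Ly6c2 was lower (540 ± 206 against 667 ± 225 CPM), and Csf1r had 215 ± 24.3 against 220 ± 27.2 CPM (adjusted p = 0.683).

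Of 14 dendritic cell markers, 5 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 6.2e-06, adjusted p = 0.189 with an estimated correlation). The list was not called in lavages 1 and 2 alone (adjusted p = 0.15, median 0.25), and its median was 0.66 in lavages 3 to 6 alone. Itgae rose from 57.2 ± 6.54 to 83.2 ± 8.23 CPM and Batf3 from 10.7 ± 2.04 to 16.7 ± 1.28 CPM, the latter not called in lavages 1 and 2 alone (adjusted p = 0.0561). Cd24a, which eosinophils also express, fell from 5017 ± 1027 to 4404 ± 865 CPM. Cd74 had 29.4 ± 23.2 against 16.3 ± 15.8 CPM (adjusted p = 0.0234), a call lost without lavage 2 (0.076), lavage 3 (0.157) or lavage 4 (0.0667), without both lavages 3 and 4 (0.378) and in lavages 1 and 2 alone (0.756).

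Neutrophil markers split. Of 15 members tested, 7 were higher and 5 lower (7 and 5 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.00591, adjusted p = 0.375 with an estimated correlation, fry adjusted p = 0.0626, camera adjusted p = 0.0676 without lavage 5 and 0.905 in lavages 1 and 2 alone). The list's median was 0.02 without lavage 2, where camera still called it (adjusted p = 0.000775). By lavage the median ran from -0.33 in lavage 4 to 0.30 in lavage 6. S100a8, S100a9 and the granule protein gene Ngp, which rose from 25.4 ± 8.45 to 46.8 ± 13.5 CPM, were higher. The most abundant members were lower: Retnlg fell from 1603 ± 236 to 1244 ± 251 CPM, Mxd1 from 722 ± 90.5 to 610 ± 89.8 CPM and Padi4 from 440 ± 35.2 to 355 ± 35.0 CPM, and Mmp9 fell as given above.

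Markers of the remaining cell types were not called as lists. Of 9 mast cell and basophil markers, 1 was higher and 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.0717, from 0.0311 to 0.0457 without lavage 1, 2, 3 or 6, and 0.0436 by fry). Kit rose from 38.1 ± 12.0 to 46.6 ± 13.2 CPM, and Ifitm1, which is also on the interferon list, fell from 6.26 ± 4.96 to 1.12 ± 0.58 CPM, as did Cd200r3 from 11.6 ± 5.77 to 6.57 ± 3.10 CPM. Il4 had 43.0 ± 2.87 against 39.6 ± 5.03 CPM and Hdc 32.1 ± 8.98 against 30.4 ± 11.02 CPM, neither called, although Il4 was called higher with library totals alone (adjusted p = 0.0278) and Hdc in lavages 1 and 2 alone (0.00098). Of 5 B and plasma cell markers 0 were called (camera adjusted p = 0.686), with Ebf1 at 13.7 against 13.1 CPM, Cd79a at 10.3 against 10.8 CPM and Cd22 at 3.72 against 3.51 CPM. Of 9 epithelial markers 1 was lower, Scgb3a1 (1.19 ± 0.96 against 3.40 ± 4.09 CPM), a call lost without lavage 5 (adjusted p = 0.105) and in lavages 1 and 2 alone (0.19). The median of that list was 0.12, its mean -0.13 and its test downward (camera adjusted p = 0.723). Muc5b had 13.2 ± 6.03 against 13.5 ± 11.3 CPM and Krt18 12.3 ± 3.59 against 13.2 ± 3.14 CPM. Clca1 had 11.9 ± 13.9 against 26.6 ± 58.2 CPM and was higher in 3 of 6 pairs, its TREM-1- mean resting on lavage 5 (145 CPM), without which the Clca1 log2 fold change was 1.29 in place of 0.12 (adjusted p = 0.266). Of 5 endothelial and stromal markers 0 were called (camera adjusted p = 0.994), Pecam1 having 209 against 222 CPM (called lower in lavages 1 and 2 alone, adjusted p = 0.00166), Acta2 8.34 against 10.3 CPM and Pdgfrb 1.72 against 1.41 CPM. The erythrocyte and platelet list had 4 tested members, too few for the test, with 0 called, and among them Itga2b had 29.8 against 30.2 CPM, Gp1bb 2.43 against 2.33 CPM and Alas2 1.19 against 1.59 CPM.

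**Figure D4:**
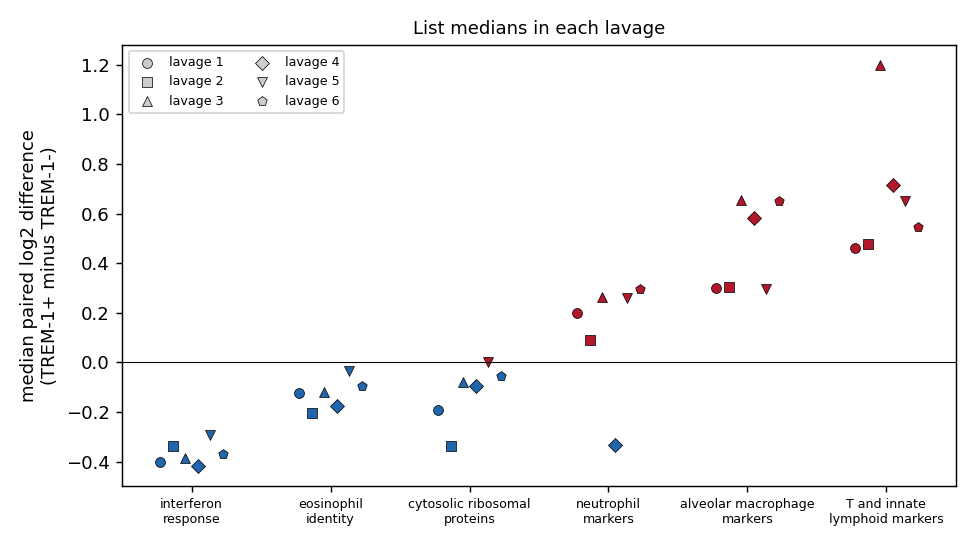
Median over list members of the paired log2 difference, TREM-1+ minus TREM-1- (y axis), for 6 lists (x axis) in each lavage (symbols), red above 0 and blue below. The interferon list lies between -0.42 and -0.29 and the T and innate lymphoid marker list between 0.46 and 1.20 in the 6 lavages, while the neutrophil list is below 0 in lavage 4, at -0.33.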

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

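Chosen only after the result was seen were the tests of the interferon list under 5 scalings and against the identity list, of the T list against other markers, and of the whole neutrophil list. Against chance, the real split was compared with the other splits that part all 6 pairs. It alone of 32 gave as many genes (1797, highest other 3), as many genes at 2-fold or more (82, highest other 1) and as many lists (16). The highest other for lists, 15, came from a split that swapped 1 lavage and so followed the fractions in 5, and splits that swapped 3 called 0 to 3 lists. Of 100 drawn splits, 1, the real one, called as many genes. The highest other called 756 and parted 4 pairs, each of them the same way. The drawn splits parted from 2 to 6 pairs. With lavage as a block only parted pairs inform the test, so this second comparison favours the real split and adds little to the first.

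The interferon response list was lower in TREM-1+ eosinophils. Among the 32 splits 1, the real one, gave a camera p as small (smallest other 4.13e-21). A trend with transcript length and GC content is argued against by its size: it carried 0.457% of the variance of log2 fold change, its lowest value in the 47 of 48 members with a length was -0.03, and the median with it removed was -0.393. Scaling is argued against as the whole cause, since the highest median over 5 scalings was -0.24. Scaling moves all genes nearly alike, so the median relative to all genes, -0.371 to -0.369, could hardly change. Dilution by RNA of other cells is argued against less firmly as the whole cause: the list's median minus that of the eosinophil identity list was -0.244. The identity list holds genes that other cells may express, such as Cd24a, and these may understate dilution. By lavage the interferon median ran from -0.42 to -0.29 and the identity median from -0.20 to -0.03. The permutation p of the difference, two-sided, was 1e-04, the smallest 10000 draws can give. It shuffled genes between the 2 lists as if independent, so it does not measure the spread between lavages. A lower interferon response in TREM-1+ eosinophils is a candidate explanation, as a hypothesis found and tested on the same data.

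T and innate lymphoid markers were higher in TREM-1+ libraries, although the gate of Siglec-F+ cells should hold back most lymphocytes. Inflated folds of low counts are argued against, since the list's median lay at percentile 100 of 10000 random lists of like expression. A lower share of eosinophils that raises all other cell types alike was not decided. The list lay 0.756 above B cell, mast cell, epithelial, platelet and stromal markers, whose lists had not been called. It lay 0.651 above all other marker lists together, those that rose included (permutation p, two-sided, 0.0012, shuffling genes as if independent). The compared lists hold genes that the sorted cells may express themselves, such as Pecam1 at a mean of 215 CPM and Cd24a at 4711 CPM. Such genes cannot report the share of other cells. Lymphocytes inside the gate may contribute and stay open: their paired differences correlated at percentile 92.29 of random lists, and those of the 14 called members at percentile 22.64 of lists of other raised genes. The bound set beforehand against this explanation, a percentile below 50, was met by the last value but was too loose, since about that share of random lists falls below it; it was replaced by 2.5 after the value was seen. The T markers also have lower counts than most raised genes, so counting noise may lower their correlation, and among the most abundant members Rora had 16.4 CPM in TREM-1+ and 14.8 CPM in TREM-1- libraries.

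Neutrophil markers split, with 7 higher and 5 of 15 lower, so the list did not rise as a whole. The 5 falls cannot decide whether neutrophils inside the gate raised the other members. Among those 5, Retnlg (1603 CPM), Mxd1 (722), Padi4 (440) and Mmp9 (275) were abundant in TREM-1- libraries. S100a8 rose from 1.70 to 8.72 CPM, and a small admixture need not raise genes of such high level. The 7 that rose, S100a8, S100a9, Ngp, Ltf, Csf3r, Ly6g and Cxcr2, correlated over the 6 lavages at percentile 99.99 of random lists and at percentile 99.81 of lists of other raised genes. A varying admixture of neutrophils could give this for those 7, and any inside the gate that carried TREM-1 would be sorted into the TREM-1+ fraction. The gate of Siglec-F+ cells with low to middle Ly6G should hold back most neutrophils but need not remove all. A shared program of eosinophils was not tested. For alveolar macrophage markers the percentile was 78.59, so macrophages inside the gate stay open, although the gate of low to middle CD11c should hold back most alveolar macrophages.

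A single library far from the other 5 of its fraction was found in 13 of 274 groups (4.74%, where chance gives 5%) by Dixon's test, in which the gap to the nearest library is divided by the range of the 6. In TREM-1- libraries these were Ccl24 (0.683), Scgb3a1 (0.794), Clca1 (0.932) and Muc5b (0.738) in lavage 5, at 15.04, 11.6, 145 and 35.6 CPM, Nedd4 (0.651) in lavage 2 at 30.1 CPM, and Ifitm1 (0.777) in lavage 4 at 16.1 CPM. In TREM-1+ libraries they were Nedd4 (0.666) in lavage 2 at 12.7 CPM, Dusp5 (0.634) in lavage 5 at 117 CPM, Mki67 (0.629) in lavage 4 at 80.6 CPM, and Itgax (0.699) and Ly6c2 (0.7) in lavage 6 at 1091 and 944 CPM. The share of counts on Gm26917 was 6.87% in the TREM-1- library of lavage 4 (0.696), and the TMM factor of the TREM-1+ library of lavage 4 was 1.13 (0.645).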

How the results depend on the processing

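Chosen after seeing the data were the fits on lavages 1 and 2, 3 to 6, and 1, 2, 5 and 6, on protein-coding genes, and with a T marker covariate. The Trem1 log2 fold change was called and lay between 1.55 and 1.75 in all settings but the T marker covariate. The interferon list was lower in each setting in which lists were tested, with its highest adjusted p, 0.00481, under an estimated correlation. The number of genes differing between TREM-1+ and TREM-1- eosinophils stayed within 1.5 times 1797 with RLE, upper-quartile factors, library totals, no filter, 5 CPM, DESeq2, limma-voom, limma-trend, protein-coding genes, and each lavage left out (1421 to 1588, at 2-fold 71 to 102, lists 16 to 17). Without the block there were 83 genes, 11 at 2-fold, all 83 among those reported, and 92 of 129 named genes lost their call. At 2-fold, library totals alone gave 139, no filter 138 and a mean of at least 5 CPM 34, which tests fewer genes of low level. An adjusted p below 0.01, a stricter threshold on the same fit, left 1178 genes. Lavages 3 to 6 alone, with fewer libraries, left 1168. Of the 1796 genes called as reported and tested in those lavages, 1796 kept their sign, though the 2 fits share libraries. How much of that drop came from fewer libraries was not tested. An estimated correlation left 1 list. Leaving out a lavage moved the granule list between 0.00993, called lower without lavage 5, and 0.963, and in lavages 1 and 2 it was called lower (0.0482) and Rpl3 was -0.0236; the cause was not tested. With the T marker covariate, which followed the fraction within lavages (r = 0.986), 5 genes, 5 at 2-fold, and 5 lists were called, and Trem1 (1.76, adjusted p = 0.232) was not, so this fit cannot separate the T marker score from the fraction. Of the 1797 genes called as reported, 1361 (75.7%) kept their sign with this covariate. Among the 129 named genes, 20 that were called in either fit had log2 fold changes of opposite sign with it: Il6st -1.03, Cd3e -0.036, Ccl24 -0.35, Atp8b5 1.74, Clec7a -0.20, Pim1 0.027, Cox7a2l 0.68, Rpl3 -0.26, Cyp51 0.16, Ctss -0.38, Atp6v0d2 -0.18, S1pr1 -0.68, H2-Ab1 -0.019, Dusp5 -0.046, Zfp36 0.071, Mcm2 -0.78, Mki67 0.49, Batf3 -0.35, Tcf7 -1.14 and Il7r -0.24. Of the lists of opposite direction in it, those called in either fit were the granule (adjusted p = 0.00325), secreted factor (0.0399), neutrophil (0.248), alveolar macrophage (0.808), dendritic cell (0.453) and T and innate lymphoid (0.808) lists. Small changes may be missed, since 58.2% of genes changed 1.5-fold in simulation were recovered. Each simulated table had 200 changed genes, against 1797 called here. Fewer changed genes make the adjustment stricter, so recovery in the real comparison may differ.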

Other observations

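Several abundant genes outside the lists also differed between the fractions; those named here were chosen after their values were seen. Hgf, encoding hepatocyte growth factor, rose from 150.5 ± 29.8 to 256.5 ± 48.5 CPM (SD, n = 6), a log2 fold change of 0.77 (edgeR adjusted p = 6.56e-16, 6 of 6 pairs). Peg10 (1.05), Tarm1 (0.99), which encodes an activating myeloid receptor, and Adpgk (0.75), which encodes a glucokinase, were also higher in 6 of 6 pairs. Olfm4 (0.72) and Itgb2l (0.68) were higher as well, both in 6 of 6 pairs. Whether neutrophils or other cells inside the gate contributed to these rises was not tested.

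Slc11a1, encoding a phagosomal metal transporter, fell from 164 ± 5.47 to 102 ± 8.17 CPM (SD, n = 6), a log2 fold change of -0.69 (edgeR adjusted p = 1.44e-12, 6 of 6 pairs). Neb (-0.90), Bltp3a (-0.75), the inhibitory lectin gene Siglecg (-0.61), the galectin gene Lgals9 (-0.56) and the hypoxia-inducible factor gene Hif1a (-0.46) were lower in 6 of 6 pairs.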
